A study of Mus musculus with 6 samples.

How the data were processed

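The 6 libraries were assigned to the mimic group or the control group (3 each) from their titles. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was captured on beads, and strand-specific paired-end libraries were sequenced on a NovaSeq X Plus. The submitters' processing notes name HISAT2, DESeq2 and the genome build GRCm39 without giving versions. The counting tool, its strand setting and the annotation release are not given in the sources used here. The authors deposited a table of read counts per gene, as whole numbers, for 24794 genes. The authors also deposited a table of FPKM values, rounded to 2 decimals, for 24494 of these genes. One column per library was used from each table. The symbols of 575 genes are written with _ where mouse nomenclature has a hyphen, and the hyphen was put back.

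Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, estimateDisp, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 13779 genes, and at most 0.071% of a library's counts fell outside them. Values given as CPM come from edgeR's cpm function with TMM-scaled library sizes. The SE of a log2 change was taken as its size divided by the square root of F. Depth was 25376993 to 32963986 counts per library. The counts of 2 libraries of the same group differed by more than sampling noise in each pair (mean chi-square per gene 1.86 to 2.22), so that each library was counted once.

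Gene lists were written before the data were examined. Those with at least 5 tested members were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Where 2 gene IDs share a symbol, the ID with more counts was kept. The genes named in the text follow a rule set at the same time. It takes the 10 risen and 10 fallen genes with the largest changes among called genes with a mean of at least 2 CPM and non-overlapping groups, skipping unnamed gene models. It adds the 5 risen and 5 fallen with the smallest adjusted p, up to 4 called members of each list, the 6 fallen genes with an 8mer site and the smallest adjusted p, the tested family targets, and Actb, Gapdh, Hprt and Tbp. Genes named outside the rule are said to be chosen after their values were seen.

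Seed sites were sought in the 3' UTRs of GENCODE M21 on GRCm38, matched by gene ID without version. The sites were an 8mer (AGCACTTA), a 7mer-m8 (AGCACTT), a 7mer-A1 (GCACTTA) or a 6mer (GCACTT), best site per gene, over 11550 protein-coding genes with a 3' UTR. For the word scan the log2 change was regressed on the presence of each 7-base word, with log UTR length and UTR GC content as covariates. Scans and permutations used numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15. Correlated words and genes make the t values descriptive.

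The steps were tested on simulated data, counts drawn for the mimic against control comparison with the real means, dispersions and library sizes and 200 changed genes among 13660 tested. Of the genes changed 1.2-fold, 58.5% were recovered, of those changed 1.5-fold 77.6%, and of those changed 2-fold 92.2%. Of 13444 unchanged genes 6 were called. A planted list of 20 genes shifted by -0.3 was recovered with a median of -0.30, while 3 of 34 other lists were also called. The changed and planted genes were drawn from all genes, members of those lists included, so these 3 calls need not be false. A word planted with a shift of -0.1 ranked 1 in the scan.

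Alternatives set before the data were examined were DESeq2 size factors within edgeR, total counts only, the DESeq2 1.42.0 Wald test, no filter, at least 2 CPM in 3 libraries, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), the replicate number as a block, each library left out, and an adjusted p under 0.01. For the seed tests the 3' UTR of the transcript with the longest coding sequence was used in turn. Alternatives chosen after seeing the data were lists without members that hold a site, removal of a trend on transcript length and GC content, total counts without mitochondrial and ribosomal genes, total counts only for the lists and seed tests, and the estimated correlation together with each other setting.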

Results

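Polyadenylated RNA was sequenced in 6 libraries of Lewis lung carcinoma cells, a transplantable line derived from a lung tumour of a C57BL/6 mouse. In 3 libraries the cells had been transfected with mimics of miR-291-3, and in 3 with a control mimic. According to the series' design text the mimic stands for miR-291a-3p, a microRNA of the miR-290 cluster that mouse embryonic stem cells express, and the question is what its overexpression does to these cells. The control libraries held 29568848, 28318155 and 32963986 counts and the mimic libraries 25376993, 28316848 and 29058948. The first principal component of the 13779 genes tested carried 53.6% of the variance and separated the 3 mimic from the 3 control libraries. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. That spread was small, with a biological coefficient of variation of 2.02%.

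Nearly equal numbers of genes rose and fell in the mimic libraries, and most changes were small. Of the 13779 genes tested, 3349 rose and 3423 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median change of the risen genes was 14.8% and that of the fallen genes -18.1%. Of the risen genes 2301 changed by less than 1.2-fold and 200 by at least 1.5-fold, against 1553 and 589 of the fallen genes. At 2-fold or more, 51 genes rose and 182 fell, counts that depend on the setting: they were 106 and 279 without a filter, 22 and 58 with at least 2 CPM in 3 libraries, 25 and 74 with limma on log2(FPKM + 0.1), and 5 and 11 with limma on log2(FPKM + 1). The balance of directions depends on the scaling: with total counts only, 2341 genes rose and 4444 fell, so that 65.5% of the called genes fell in place of 50.5%, and the median of all tested genes moved to -0.06 on the log2 scale.

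Ctxnd1 (ENSMUSG00000097789.3, chromosome 7) fell from 32.2 ± 1.18 to 6.35 ± 0.526 CPM (SD, n = 3 each), a log2 change of -2.35 ± 0.07 (SE). Cavin3, a component of the caveolar coat, fell from 44.5 ± 0.884 to 14.6 ± 0.151 CPM, and Ehd2, an ATPase found at the neck of caveolae, from 87.1 ± 0.81 to 38.3 ± 1.83 CPM. Rpia, the ribose 5-phosphate isomerase of the pentose phosphate pathway, fell by 1.61 on the log2 scale. Mmp3, which encodes the matrix protease stromelysin, fell by 1.72, the carbonyl reductase Cbr2 by 2.18, the cytokine gene Il7 by 1.55 and the amyloid precursor gene App by 1.46. Galnt15 fell by 1.57, the scavenger receptor Scara5 by 1.41 and the immunoproteasome subunit Psmb8 by 1.56. Citrate synthase, Cs, fell from 503 ± 2.35 to 337 ± 4.7 CPM, and the chromatin protein Hp1bp3 fell by 0.87 on the log2 scale.

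Among the genes that rose, Akr1b1, which encodes aldose reductase, had the smallest adjusted p (6.33e-23, edgeR) and went from 497 ± 24.7 to 1077 ± 60 CPM. Mcam, a cell adhesion molecule first described in melanoma, rose 5.28-fold from a low level of 0.71 ± 0.104 CPM, and Matn3, a cartilage matrix protein, rose 4.41-fold from 0.76 ± 0.393 CPM. Better expressed genes with large increases were Anxa6 (6.97 to 21.4 CPM, 3.07-fold), the imprinted gene Mest (14.7 to 39.9 CPM, 2.71-fold) and the matricellular gene Ccn1 (24.7 to 59.2 CPM, 2.40-fold). Col7a1, the collagen of anchoring fibrils, rose 2.29-fold and Aif1l 2.18-fold. Taldo1, the transaldolase of the pentose phosphate pathway, rose 1.77-fold while Rpia of the same pathway fell. The reference genes Actb, Gapdh and Hprt rose by 0.26, 0.20 and 0.17 on the log2 scale and also rose under every scaling tried. Tbp rose by 0.11, a change that was not called with total counts only (adjusted p = 0.207, edgeR).

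Genes that earlier work on other cells had named as targets of microRNAs with this seed fell as a group. Of 23 tested members, 16 fell, 1 rose and 6 did not pass, and adjusted over the list alone 17 fell and 1 rose. The cell cycle inhibitor Cdkn1a fell from 21.7 ± 1.4 to 9.98 ± 0.566 CPM (log2 change -1.12 ± 0.07, SE), the retinoblastoma-related gene Rbl2 from 31.5 ± 1.46 to 14.9 ± 1.07 CPM and the TGF-beta receptor gene Tgfbr2 from 33.4 ± 1.25 to 16.2 ± 0.955 CPM. The transcription factor gene Irf2, Casp2 and the Hippo kinase gene Lats2 fell by 0.83, 0.72 and 0.57 on the log2 scale. Not all members moved: Ccnd2, Txnip and Wee1 had log2 changes of 0.04, 0.00 and -0.04 that did not pass, and Kdm1a rose by 0.09, a call that was lost with total counts only. The list was lower against the other genes with camera's preset correlation (adjusted p = 5.15e-14) and with an estimated correlation (adjusted p = 0.0409). Of the 23 members, 22 hold a 7-base or 8-base seed site in the 3' UTR.

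**Figure D1:**
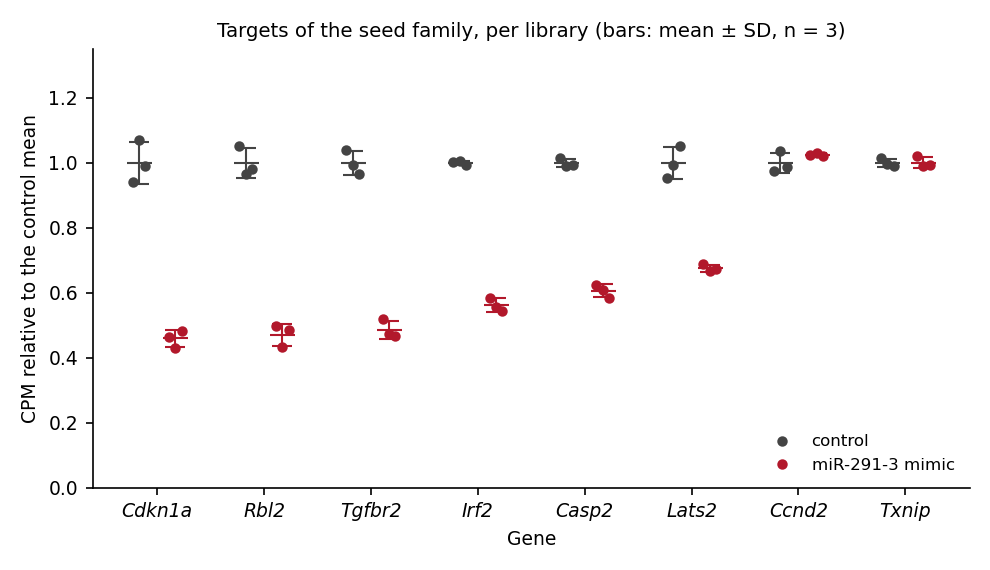
CPM of 8 listed targets of the seed family in each library (points), divided by the control mean, with the group mean and SD as bars (n = 3 per group). Cdkn1a, Rbl2, Tgfbr2, Irf2, Casp2 and Lats2 lie below the control libraries in all 3 mimic libraries, while the points of Ccnd2 and Txnip overlap those of the control libraries.

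Genes whose 3' UTR matched the seed of miR-291a-3p were lower in the mimic libraries than genes without a match, and most so with the longest match. Sites were sought in the GENCODE M21 annotation of GRCm38, which is not the build of the deposited values. The 416 genes whose best site was an 8mer, AGCACTTA, had a median log2 change of -0.13. The 1631 genes with a 7mer-m8 site had -0.06, the 371 with a 7mer-A1 site -0.06, the 1438 with a 6mer -0.02, and the 7694 with none 0.02. Of the 8mer genes 205 fell (49.3%) and 54 rose, against 23.6% fallen and 30.7% risen among genes with none. The 8mer class was lower with the preset correlation (adjusted p = 1.17e-08, camera) and with an estimated correlation (adjusted p = 0.0107), and so was the 7mer-m8 class (adjusted p = 0.00949, and adjusted p = 0.0347 with an estimated correlation). The 7mer-A1 class passed with the preset correlation (adjusted p = 0.0217) and not with an estimated correlation (adjusted p = 0.111), and the 6mer class passed with neither. With the replicate number as a block neither the 8mer class (adjusted p = 0.0668) nor the 7mer-m8 class (adjusted p = 0.201) passed with an estimated correlation. The 7mer-m8 class also did not pass with an estimated correlation without control replicate 3 (adjusted p = 0.0744), mimic replicate 1 (0.0685) or mimic replicate 3 (0.0565).

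Taking 7-base and 8-base sites together, 38.7% of 2418 genes with a site fell, against 24.6% of 9132 without (odds ratio 1.93, 95% interval 1.76 to 2.12, Fisher's exact test, two-sided, p = 5.07e-41). Fewer genes with a site rose, 18.1% against 29.8% (odds ratio 0.52, interval 0.465 to 0.583). The median log2 change was -0.06 in genes with 1 site, -0.08 with 2 and -0.13 with 3 or more. Most fallen genes held no such site: 29.4% of the 3182 fallen genes with an annotated 3' UTR held a 7-base or 8-base site, and 38 of the 138 that fell at least 2-fold (27.5%), against 20.9% of all 11550 tested. These genes are not independent replicates, and the Fisher test treats them as if they were.

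**Figure D2:**
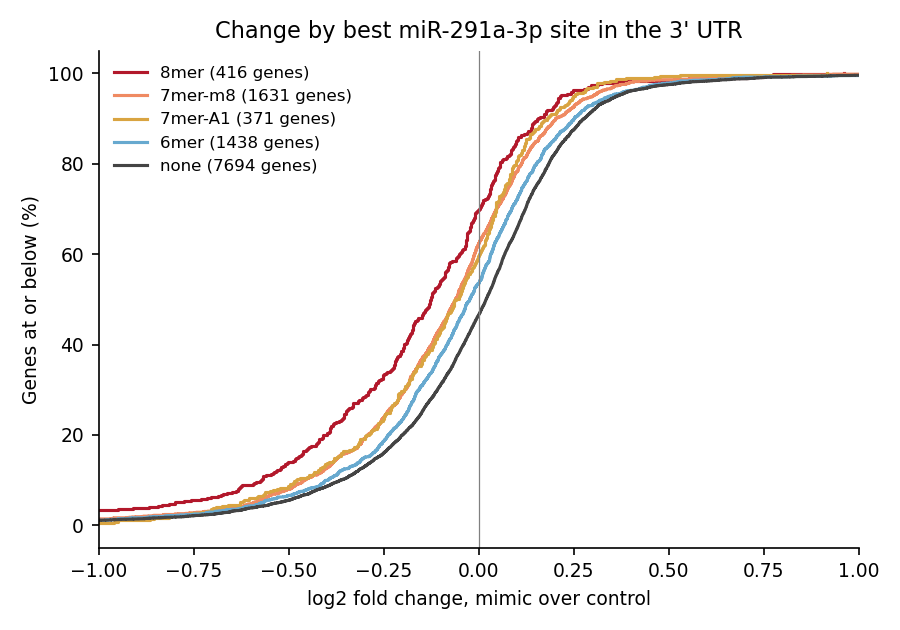
Cumulative share of genes (percent) against log2 fold change, mimic over control, for genes grouped by the best miR-291a-3p site in the 3' UTR. The 416 genes with an 8mer site lie farthest to the left (median -0.13) and the 7694 genes with none farthest to the right (median 0.02).

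The 6 fallen genes with the smallest adjusted p among those with an 8mer site were Ctxnd1, Cavin3, Ehd2, Hp1bp3, Cs and Rpia. In Ctxnd1 the 8mer lies at positions 84577702 to 84577709 of chromosome 7 (GRCm38), bases 614 to 621 of a 3' UTR of 6443 bases. Cavin3 has it at 105480748 to 105480755 of chromosome 7, bases 66 to 73 of 738. Ehd2 has 2 copies on chromosome 7, at 15950053 to 15950060 and 15949679 to 15949686. In Hp1bp3 the site lies at 138242088 to 138242095 of chromosome 4, in Cs at 128362210 to 128362217 of chromosome 10, and in Rpia at 70765853 to 70765860 of chromosome 6. Each of these sites is exonic and inside the annotated 3' UTR.

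The seed match also stood apart among all 7-base words. Among 16118 words, each tested for its presence in the 3' UTR with UTR length and GC content as covariates, AGCACTT, the 7mer-m8 match of miR-291a-3p, had the most negative t (-10.7, in 2047 UTRs). GCACTTA, a 7mer-A1 match that miR-291a-3p and miR-291b-3p share, ranked 2 (t = -9.49). Matches of related seeds that share 6 of these bases followed: GCACTTT of the miR-17 family ranked 4 (t = -7.48) and TGCACTT of miR-291b-3p ranked 5 (t = -6.68). The words of miR-291a-5p, the opposite arm of the natural hairpin, had t values of -1.07 and 1.83. The labels do not give the mimic's own sequence, so the other strand of the transfected duplex was not tested.

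**Figure D3:**
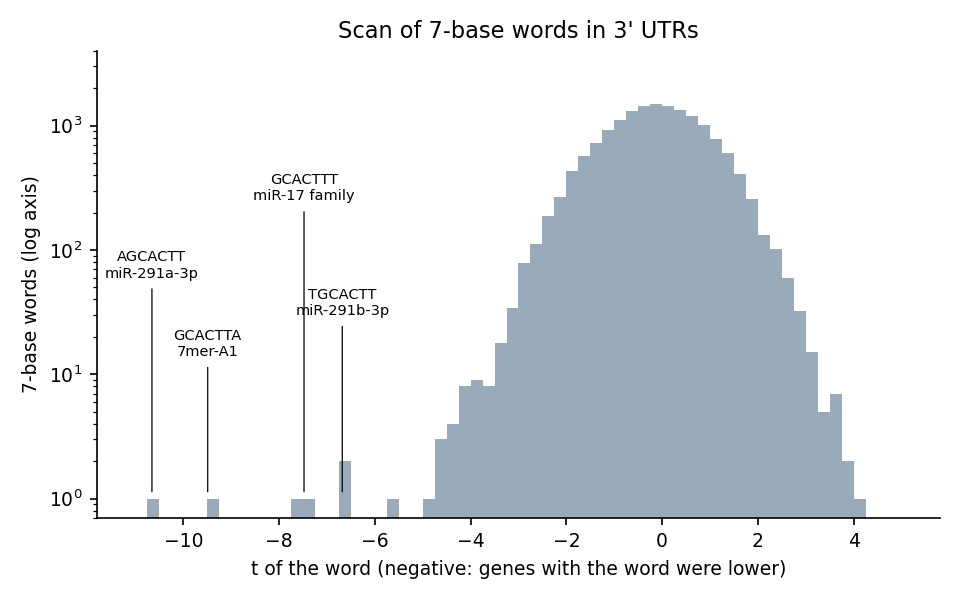
Number of 7-base words (log axis) by their t in the regression of log2 fold change on the presence of the word in the 3' UTR, over 16118 words. The words AGCACTT and GCACTTA, which match the seed of miR-291a-3p (GCACTTA also that of miR-291b-3p), lie at -10.7 and -9.49, apart from the bulk.

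Genes that drive the cell cycle and genes that restrain it were both lower in the mimic libraries. In the list for DNA replication and the G1/S step 27 of 32 members fell and 1 rose, and adjusted over the list alone 28 fell and 1 rose. The risen member, Mcm2 (log2 change 0.06), was chosen after its value was seen and was not called with total counts only. E2f2, an activator of S-phase genes whose 3' UTR holds an 8mer site, fell from 28.5 ± 1.47 to 13.9 ± 1.58 CPM. Its log2 change of -1.04 was the lowest of the list, whose median was -0.16. The ribonucleotide reductase gene Rrm2, Rfc3 and Lig1 fell by 0.30, 0.39 and 0.30 on the log2 scale. Inhibitors of cyclin-dependent kinases and other brakes on G1 fell as well, 9 of 11 (9 also adjusted over the list alone). Among them were Cdkn2c (56.7 ± 1.13 to 28.5 ± 1.45 CPM), Rbl1 (log2 change -0.59), and Cdkn1a and Rbl2, which the list of family targets holds too. The G1/S and CDK inhibitor lists passed with the preset correlation (adjusted p = 1.5e-08 and 2e-10, camera) and with an estimated correlation (adjusted p = 0.0409 and 0.0479). In the G2/M and mitosis list 22 of 32 fell and 3 rose (23 and 3 adjusted over the list alone), with Ccnb2 (log2 change -0.48), the proliferation marker Mki67 (-0.38), Nusap1 (-0.45) and Top2a (-0.25). That list passed with the preset correlation (adjusted p = 1.3e-06) but not with an estimated correlation (adjusted p = 0.14). The 3 that rose, Aurka (0.08), Plk1 (0.06) and Birc5 (0.06), were chosen after their values were seen, and none rose with total counts only.

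Genes of MHC class I antigen presentation and of the interferon response were lower in the mimic libraries. Of 15 antigen presentation genes 13 fell and none rose, the same counts as adjusted over the list alone: Psmb8 fell from 13.8 ± 0.564 to 4.66 ± 0.214 CPM, the peptide transporter gene Tap2 from 35.7 ± 1.13 to 18.6 ± 0.254, and Tapbp from 111 ± 0.71 to 66.9 ± 1.61. H2-D1 fell by 0.39 on the log2 scale, though its reads may be split with other class I genes of near-identical sequence. The list passed with both correlations (adjusted p = 6.13e-12 and 0.0409, camera). Of 19 interferon response genes 16 fell and none rose, also when adjusted over the list alone, including Isg20 (log2 change -0.62), Ifi35 (-0.61) and the RNA sensor gene Rigi (-0.51). The interferon list passed with the preset correlation (adjusted p = 0.00253) and not with an estimated correlation (adjusted p = 0.14). Of the macrophage and other leukocyte markers, 2 of 5 tested also fell, Lyz2 from 5.52 ± 1.47 to 2.78 ± 0.338 CPM and Cd14 from 9.62 ± 0.847 to 6.31 ± 0.779.

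Most called genes of the glycolysis, cytoskeleton, NRF2, ribosome and respiratory chain lists rose by small amounts. In the hypoxia and glycolysis list 19 of 27 rose and 2 fell (19 and 3 adjusted over the list alone), with the glucose transporter gene Slc2a1 (1.42-fold), Adm (1.44-fold), Pkm (1.24-fold) and Eno1 (1.24-fold). Of 32 actin and migration genes 16 rose and 4 fell, as when adjusted over the list alone. Myh9 rose 1.37-fold and Fscn1 1.29-fold, and Cfl2 fell by 0.69 on the log2 scale. NRF2 targets had 14 risen and 5 fallen of 22, again as when adjusted over the list alone, with Taldo1, Gsto1 (1.34-fold) and Hmox1 (1.65-fold). All 33 ribosomal protein genes rose, by a median of 0.12 on the log2 scale, as did 20 of 28 nuclear genes of the respiratory chain (1 fell), with equal counts adjusted over the list alone. Of the 13 mitochondrially encoded mRNAs 10 fell and 1 rose, also when adjusted over the list alone, and mt-Cytb fell by 0.23 and mt-Co1 fell by 0.21 on the log2 scale. These mRNAs took 3.68% ± 0.0644 of control counts and 3.15% ± 0.0315 of mimic counts (SD, n = 3), and ribosomal RNA genes 0.107% ± 0.0224 and 0.0635% ± 0.00812. Members that went against their list, chosen after their values were seen apart from the family target Rhoc, were Pdk1 (-0.42) and Vegfa (-0.16) for hypoxia, Rhoc (-0.28), Limk2 (-0.18) and Arpc5 (-0.11) for actin, Nqo1 (-0.47), Gstm1 (-0.34), Srxn1 (-0.31), Nfe2l2 (-0.18) and G6pdx (-0.11) for NRF2, Ndufv1 (-0.06), and mt-Co3 (0.44). Each of these 6 lists passed with the preset correlation, and none with an estimated correlation (adjusted p = 0.245, 0.144, 0.245, 0.215, 0.215 and 0.215, in the order given).

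With total counts only in place of TMM, an alternative chosen for the lists after seeing the data, 16 genes of the hypoxia and glycolysis list rose and 8 fell, 14 and 8 of the actin list, 10 and 7 of the NRF2 list, 21 and 0 of the ribosomal protein list, and 13 and 3 of the respiratory chain list. The preset correlation may be lenient, which the simulated data cannot decide. There it also called 3 of 34 lists that were not planted. However, the changed genes could be members of those lists, and each gene was drawn independently of the others. With the preset correlation 12 of 34 lists passed in the real grouping, and between 7 and 10 in the other groupings of the 6 libraries into 3 and 3. Each other grouping mixes mimic and control libraries on both sides. Part of the mimic effect stays between the sides and the rest adds to the spread within them, so these counts decide nothing. With an estimated correlation 4 lists passed in the real grouping and 0 in each other grouping, where the same limit holds. Those 4, the family targets, the G1/S genes, the CDK inhibitors and the MHC class I genes, did not pass with an estimated correlation when any single library was left out, a check chosen after seeing the data (adjusted p between 0.0618 and 0.131). Fewer libraries leave fewer degrees of freedom, and the median log2 changes moved little: from -0.32 to -0.30 for the family targets (-0.32 with all 6 libraries), from -0.17 to -0.15 for G1/S (-0.16), from -0.57 to -0.51 for the CDK inhibitors (-0.56) and from -0.40 to -0.36 for MHC class I (-0.39). All 4 passed with the preset correlation in each case. With an estimated correlation none of the 4 passed with the replicate number as a block (adjusted p between 0.287 and 0.297). The family targets and the CDK inhibitors also did not pass with total counts only (adjusted p = 0.0547 and 0.0608) or with at least 2 CPM in 3 libraries (adjusted p = 0.0684 and 0.104).

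**Figure D4:**
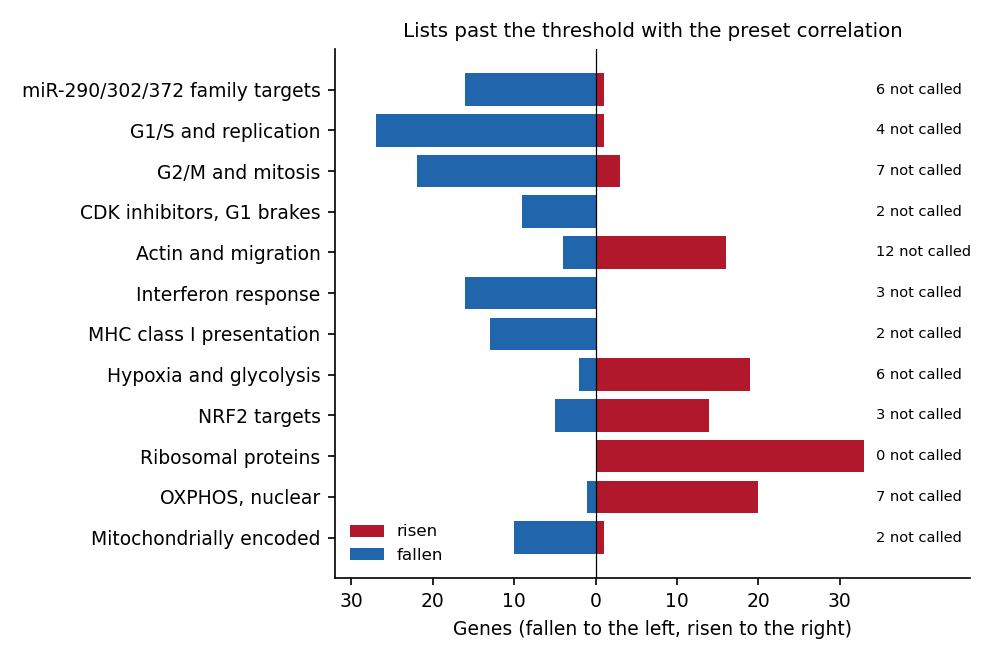
Number of genes that fell (left) and rose (right) in the 12 lists that passed with camera's preset correlation, with the members that did not pass at the right. In the G1/S list 27 genes fell and 1 rose, and all 33 ribosomal protein genes rose (21 with total counts only).

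Lists tied to invasion went in both directions. Of 20 mesenchymal genes 7 rose and 8 fell: Sparc rose 1.50-fold, while Fn1 fell from 114 ± 4.88 to 64.1 ± 2.1 CPM and S100a4 and Col3a1 fell by 0.73 and 0.37 on the log2 scale. Of 22 extracellular proteases and their inhibitors 9 rose and 9 fell, among them Ctsb, Timp1 and Mmp3, with log2 changes of -0.29, -0.28 and -1.72. In the epithelial junction list 7 of 11 rose and 3 fell, with Jup up 5.41-fold from 0.624 ± 0.155 CPM, Krt18 1.87-fold and Tjp1 with a log2 change of 0.43. Among those that fell were Ocln (-0.48) and Pkp3 (-0.26), chosen after their values were seen. The mesenchymal, protease and junction lists did not pass (adjusted p = 0.624, 0.575 and 0.059, camera). The junction list passed with total counts only (adjusted p = 0.0347), without control replicate 1 (adjusted p = 0.0455) and without mimic replicate 2 (adjusted p = 0.0346). Adjusted over the list alone 8 mesenchymal genes rose and 8 fell, while the other lists kept their counts, and the mesenchymal list's mean log2 change (0.07) and median (-0.00) differ in sign. With any single library left out the mesenchymal median was between 0.01 and 0.08. The filter was rerun in each case and left 13978 to 14041 genes, so the members of a list could differ from those with all libraries.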

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

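Alternatives that left out genes with sites, removed a length and GC trend, left mitochondrial and ribosomal genes out of the totals, used total counts only for lists and sites or joined an estimated correlation to another change were chosen after seeing the data. The numbers of genes that rose and fell stayed within 1.5 times of 3349 and 3423 in every alternative but limma on log2(FPKM + 1) without a filter, which gave 1948 risen genes and tests more genes. With each library left out in turn, 3029 to 3249 genes rose and 2977 to 3142 fell. The counts at 2-fold, 51 risen and 182 fallen, depended more on the setting: 106 and 279 without a filter, 22 and 58 with at least 2 CPM in 3 libraries, 25 and 74 with limma on log2(FPKM + 0.1), and 5 and 11 with limma on log2(FPKM + 1) with or without a filter. A pseudocount lowers the fold change of weakly expressed genes, and the stricter filter removes them. Of the 12 lists that passed with the preset correlation, 4 passed with an estimated correlation, and none of these 4 with any library left out (adjusted p 0.0618 to 0.131), while fry, which does not compare a list with other genes, called 29. The lists were also tested without members that hold a site longer than GCACTT. The G1/S, CDK inhibitor, interferon and MHC class I lists then passed with the preset correlation (adjusted p = 1.33e-05, 9.28e-05, 0.0117 and 5.57e-11). They did not pass with an estimated correlation (adjusted p = 0.104, 0.177, 0.177 and 0.104). With the length and GC trend removed the NRF2 list did not pass (adjusted p = 0.0521). Of the 172 genes taken by the naming rule none had a call reversed in an alternative, and at most 6 lost their call in any of them. The 8mer genes had a lower median than genes without a site, and AGCACTT ranked 1, in each alternative run for the sites, which did not include the settings without a filter or on FPKM. Whether replicate numbers pair the libraries is open: same-numbered libraries had correlations of 0.057, 0.042 and 0.057 over 9160 genes, and differently numbered ones -0.0499 to -0.0076. Each library correlated best with its own number, which is a hint from the data and not from the design. With the replicate block 3403 genes rose and 3484 fell, 52 and 180 of them by 2-fold, and the 8mer class passed with the preset correlation but not with an estimated correlation (adjusted p = 0.0668), as was so for the 4 lists (adjusted p 0.287 to 0.297). Depth limits the weakest genes: Mcam, Matn3 and Jup have means under 1 CPM in the control libraries.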

Other observations

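All tests of explanations below were chosen after the results they bear on were seen. The remaining lists did not pass with TMM and all 6 libraries. Under alternatives the lysosome list passed with total counts only (adjusted p = 0.00993) and without control replicate 2 (0.0495). The MAPK list passed without control replicate 1 (0.049) or mimic replicate 1 (0.0445). The TGF-beta list passed without members that hold a site longer than GCACTT (0.0119). Of 22 p53 target genes 8 fell and 1 rose (adjusted p = 0.0842, camera), with Ccng1, Ei24 and Sesn1 lower by log2 changes of -0.63, -0.28 and -0.44. Of 25 MAPK genes 10 rose and 4 fell (adjusted p = 0.0581), Myc rising 1.31-fold and Dusp5 1.68-fold, and of 24 TGF-beta response genes 10 rose and 4 fell (adjusted p = 0.0761). Adjusted over the list alone the fallen and risen genes were 10 and 3 for p53, 4 and 11 for MAPK, 10 and 6 for apoptosis, 8 and 1 for sterol synthesis, 8 and 13 for the unfolded protein response and 3 and 3 for fibroblast markers, and the other lists kept their counts. Lysosome genes (9 fallen, 7 risen of 29, adjusted p = 0.0599) included Lamp2 and Gabarap, lower by -0.48 and -0.47. The apoptosis list had 9 fallen and 5 risen of 23, the Hippo list 8 and 9 of 20, the Wnt list 8 and 3 of 18, the PI3K and mTOR list 8 and 9 of 24, the microRNA machinery list 5 and 10 of 21, and the NF-kappaB list 6 and 3 of 18. Sterol synthesis had 9 fallen and 1 risen of 22, fatty acid genes 9 and 7 of 22, unfolded protein response genes 8 and 11 of 26, immediate-early genes 4 and 6 of 16, angiogenic factors 5 and 3 of 17, pluripotency genes 1 and 3 of 7, and replication-dependent histones 1 and 5 of 22. Fibroblast markers had 3 fallen and 2 risen of 6, lung epithelium markers 2 fallen of 3, and none of 2 endothelial and 2 blood or muscle markers passed. The adjusted p was 0.0761 for the fibroblast markers and 0.297 for the leukocyte markers, and for the lists from apoptosis to histones it lay between 0.218 and 0.846. With total counts only the balance moved: the fallen and risen genes were 9 and 9 for MAPK, 4 and 6 for TGF-beta, 9 and 7 for Hippo, 10 and 5 for PI3K, 6 and 3 for microRNA machinery, 12 and 4 for fatty acids, 8 and 9 for the unfolded protein response and 13 and 4 for the lysosome. In the PI3K, microRNA machinery and fibroblast lists the mean and the median log2 change differ in sign (-0.04 and 0.05, -0.06 and 0.05, 0.03 and -0.02). With total counts only the PI3K and microRNA machinery medians were -0.01 and -0.00, and the fibroblast median was 0.33, 0.29 and 0.34 without control replicate 1, 2 or 3 and 0.30 without mimic replicate 3. The filter was rerun with each library left out, so the fibroblast list may have held other members there. These medians do not isolate the effect of a single library.

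In the pentose phosphate pathway Rpia fell 3.05-fold while Taldo1 rose 1.77-fold. The double-stranded RNA binding partner of Dicer, Prkra, had a log2 change of -0.96.

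The fall of genes with a seed site is a pattern that a technical trend could imitate, since genes with long 3' UTRs hold more words of every kind. With UTR length and GC content as covariates the slope on an 8mer site was -0.173 ± 0.0163 (SE), so these trends do not account for the whole shift. Sites of the miR-17 family, which share 6 bases, had a weaker slope: AGCACTT minus GCACTTT was -0.0349 ± 0.0161 (SE) in a joint regression. Genes with a single miR-291a-3p site differed from genes with a single miR-17 match by -0.0462 (permutation test, two-sided, p = 0.0124). The miR-291a-3p genes there included 8mers. Single 8mers had a median log2 change of -0.149 (178 genes), and single AGCACTT sites without a final A had -0.0452 (883 genes). How much of the difference rests on the 8mers was not tested. For miR-291b-3p the tests did not agree, and the order in which they were run matters. The first, on genes with a single site, gave a difference of -0.0268 (permutation test, two-sided, p = 0.0713) and did not pass; the joint regression, run afterwards, gave -0.0306 ± 0.0122, so that miR-291a-3p and miR-291b-3p sites cannot be told apart from these libraries.

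The fall of MHC class I and interferon response genes may be indirect. Of the 29 fallen members 7 (24.1%, exact 95% interval 10.3% to 43.5%) hold a 7-base or 8-base site, and the 26 members without such a site had a median log2 change of -0.62, which argues against sites in the members themselves as the whole cause. Of the 17 leukocyte markers listed, C1qa, Cd3e, Ms4a1 and S100a9 are not among the deposited genes under these symbols. The others summed to 18.9 CPM in the control and 12 CPM in the mimic libraries. The control sum was above 5% of the summed fall of H2-D1 (380 to 290 CPM), Tapbp (111 to 66.9) and B2m (log2 change -0.32, chosen after its value was seen), the limit set for excluding RNA of leukocytes. Most of that sum came from Lyz2 (5.52 CPM) and Cd14 (9.62). Ptprc, Adgre1, Itgam and Tyrobp, chosen after their values were seen, had 4, 7, 8 and 3 counts over the 3 control libraries and 0 over the mimic libraries. C1qb and S100a8, chosen likewise, had counts in both groups (8 and 5, and 12 and 7). Counts this low argue against a large share of leukocyte RNA. A small share in the control libraries and the source of Lyz2 and Cd14 remain open. A stronger response to the control duplex is open too: the 15 interferon genes too weak to be tested had a mimic over control ratio of 0.528 in summed counts corrected for depth (exact interval 0.429 to 0.648, for counting error only and not the spread between libraries), and without untransfected cells this cannot be told apart from an effect of miR-291a-3p.

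Genes with words of let-7 and miR-29 in the 3' UTR were higher than other genes: the let-7 word CTACCTC had t = 3.24 and the miR-29 word TGGTGCT t = 3.57. These words ranked 16 and 9 from the most positive of 16118 words, whose highest t was 4.18. Over 20 families their adjusted p was 0.00794 and 0.00353 (normal approximation to t). The 20 families were listed after the scan had been seen, so these values do not allow for the choice among all words. The family with the smallest adjusted p went the other way: the word TTGCACT of the miR-130 family had a lower mean (t = -3.89, adjusted p = 0.00203). In genes without a miR-291a-3p site longer than GCACTT its t was -2.48. Genes with GCACTT, the shortest match, were kept there. TTGCACT followed by T holds GCACTT, so this t may include sites of the mimic itself. Of words made of the same bases as a let-7 or miR-29 word at most 0.952% reached as high a t, the word itself included. The let-7 and miR-29 words had been chosen for a high t, so base composition remains open. A hypothesis is that the mimic displaces endogenous microRNAs in general. In genes without a miR-291a-3p site longer than GCACTT the 18 other families had a mean t of 0.568. That was farther from the mean of 10000 draws of equally common words than all but a share of 0.035 of them (two-sided). Over all genes their mean t was -0.0963 (share 0.98), so the hypothesis remains open, and microRNA levels were not analysed here.

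Other groupings of the 6 libraries are too few for a share under 0.05: they make 10 splits, and the real split was the 1 with the highest value for each measure. The real split called 6772 genes, 233 of them at 2-fold, and the other splits 0 of either. For lists with the preset correlation the values were 12 and at most 10, and for the 8mer difference in median log2 change -0.146 and at most 0.0575 in size. Every other split mixes mimic and control libraries on both sides. A mimic effect then adds to the spread within a side, which lowers the calls, and part of it stays between the sides. The other splits therefore do not stand for libraries without an effect, and the comparison decides nothing.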
